A study of Mus musculus with 4 samples.

How the data were processed

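The series held 4 single-cell libraries of mouse brain, 2 from Flox control and 2 from Ms4a3 cKO mice, taken 3 days after tMCAO. Per the labels' design text, mice received tamoxifen and a 3-day washout before surgery. Per the labels' protocols, tissue was digested with papain and DNase, red blood cells were lysed, and libraries were made with the BD Rhapsody whole-transcriptome workflow and sequenced on a DNBSEQ-T7 instrument. Per the submitters' processing notes, reads were trimmed with fastp 0.24.0 and counted with STARsolo on mm10; the version of STARsolo, the annotation and the barcode filter are not given in the sources used here. The deposited values are raw UMI counts per gene and cell barcode for 31253 genes, not normalized, and no barcode in the files had fewer than 500 UMIs. The files also give each barcode's sequence and each gene's identifier and symbol. Groups were taken from the sample titles.

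A barcode was kept with at least 500 UMIs, at least 250 genes and under 20% mitochondrially encoded UMIs, which left 60942 of 63181 barcodes. Predicted doublets were called per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 6%, and 1446 were removed (2.19, 2.56, 2.63 and 2.08% of Flox control 1 and 2 and Ms4a3 cKO 1 and 2), leaving 59496 cells. Across libraries 15 barcode sequences recurred. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and cells were clustered with the Leiden algorithm (leidenalg 0.10.2) at resolution 1 on a graph of 15 neighbours in 30 principal components, with no batch integration. Clusters were named by hand after their markers were seen, from marker genes fixed before the data were examined; a cluster stayed unnamed where its leading genes went against the name, where fewer than 3 markers were detected, or where its UMI counts were low and none of its markers stood among its top 10 genes. This left 4 clusters (7.33, 7.57, 5.41 and 7.37% of cells) without a name: clusters 8 and 30 for low UMI counts, cluster 21 because microglial and monocyte-macrophage markers scored the same, and cluster 31 because its leading genes belonged to no marker list. Cluster 11 kept an oligodendrocyte name on its 9 detected markers although its top 10 genes held none of them and 1 marker of fibroblasts, Apod, so the oligodendrocyte clusters were compared by number and not together. The names are rebuilt from the counts and are not the authors' own.

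UMI counts were summed per library and class, since cells are not replicates, and the genotypes were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with the Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05; a class was tested with at least 50 cells in every library. Log2 fold changes are cKO over Flox, with a standard error derived from the F statistic. DESeq2 1.42.0 was the other tool. Of 25 gene lists fixed before the data were examined, the sex-linked genes served only as a check on samples, and 24 were tested with camera (limma 3.58.1; preset correlation 0.01, and an estimated correlation) and fry where at least 5 members were measured. The difference between the genotype effects of monocyte-macrophages and microglia was an interaction term in 1 fit with library as a block. Shares of cells were tested with edgeR on cell numbers, with the library total as offset. Coordinates of Htr2b and Ms4a3 came from the GENCODE annotation of GRCm38, the build that mm10 names. Poisson intervals are exact at 95% and, like floors of 3 UMIs, cover counting error only. Depth per library was between 77580518 and 105566650 UMIs.

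The genes named in the text followed a rule fixed before the data were examined: Htr2b and Ms4a3; the 12 genes with the largest change in each direction among those that passed with a mean of at least 20 CPM and both libraries of a group above both of the other, leaving out sex-linked genes, Gm and Rik symbols and mitochondrially encoded genes; where fewer than 5 passed, the 5 with the smallest p; the 4 members with the smallest p of each list that passed camera; and in other classes the 3 with the smallest adjusted p in each direction. The rule named 54, 60 and 30 genes in microglia, monocyte-macrophages and neutrophils; examples in the text were taken from these, and every named gene whose sign changed under another setting is given in the closing section whether or not the results name it. Alternatives fixed in advance were DESeq2's size factors, DESeq2, no filter on low counts, a mean of at least 50 counts, doublets kept, under 10% mitochondrial UMIs, at least 1000 UMIs per cell, Leiden resolutions of 0.5 and 2, each library left out, the replicate number as a block, thinning of each cell to 1000 UMIs, other set tests and other denominators for shares. Fits of single clusters, monocyte-macrophages without clusters 5 and 25, a crossed block, and DESeq2 for Htr2b were added after the data were seen. DESeq2 was not run for the interaction.

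The tests were tried on simulated counts drawn with the means, library sizes and gene-wise spread of the real data, with 100 genes changed by 2 fold and 100 by 4 fold in each class. Each gene was drawn independently with 1 spread for both genotypes, so differences between replicates that many genes share were absent. The shares recovered can therefore lie above those of the real data. The count test made 12, 11 and 1 false calls for microglia, monocyte-macrophages and neutrophils. Of 5 lists raised among 20, camera with the preset correlation found 5 in each class with 0, 1 and 1 false calls, camera with an estimated correlation found 0 in each class, and fry found 5, 5 and 0 with 1, 0 and 0 false calls. Since genes were drawn independently, these numbers cannot show how many false calls the preset correlation gives for lists with correlated members. In the real data the estimated correlation ran from -0.0534 to 0.79 in microglia. It ran from -0.117 to 0.984 in monocyte-macrophages and from -0.0978 to 0.947 in neutrophils. The interaction was tried on 12847 simulated genes, of which 98 were changed by 2 fold and 99 by 4 fold, and made 8 false calls.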

Results

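Single-cell RNA sequencing was carried out on the brain hemisphere on the injured side, 3 days after transient middle cerebral artery occlusion (tMCAO, a mouse model of ischemic stroke in which a brain artery is blocked for a limited time and then reopened). The study set 2 libraries from Htr2b flox/flox control mice (Flox control) against 2 libraries from mice in which Htr2b, the gene for the serotonin receptor 5-HT2B, was to be deleted through Ms4a3-Cre (Ms4a3 cKO). Ms4a3 is active in granulocyte and monocyte progenitors, so that the Cre is meant for infiltrating monocyte-derived cells and neutrophils rather than for resident microglia. The labels also name tamoxifen and an ERCre for these mice, so which Cre allele acted, and whether it spared microglia, cannot be read from them. Cells were loaded without enrichment for any cell type on the BD Rhapsody platform, which captures cells in microwells and tags each mRNA at its 3′ end with a cell barcode and a unique molecular identifier (UMI). The matrices held 14007 and 17097 barcodes for Flox control 1 and 2 and 15756 and 16321 for Ms4a3 cKO 1 and 2, with totals of 105566650, 105545311, 77580518 and 84397197 UMIs. After filtering, 13219, 16091, 14884 and 15302 cells were kept, with a median of 6602, 5522, 3764 and 4004 UMIs per cell, so that the cKO libraries were shallower. The labels do not say that the libraries came from separate animals, and p-values therefore measure only the spread between these samples, which may be technical. Xist lay between 0 and 0.0621 and Ddx3y between 159 and 217 CPM in all 4 libraries. CPM are a gene's UMIs scaled to a common library total.

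The 59496 kept cells fell into 34 clusters, of which 30 were given a name from marker genes fixed before the data were examined. Clusters were called microglia-like, monocyte-macrophage-like and so on, and are given by the class name alone from here on. The largest cluster of a class differed between libraries. For microglia it was cluster 2 in Flox control 1 (3055 of 5041 cells) and cluster 0 in the other 3 libraries (1860 of 4187, 2849 of 4507 and 3163 of 5939 cells). Monocyte-macrophages lay in cluster 5 in Flox control 1 (2634 of 3587 cells), in cluster 3 in Flox control 2 (2970 of 4183 cells), and in cluster 4 in Ms4a3 cKO 1 and 2 (1769 of 2816 and 1035 of 1498 cells). Neutrophils lay in cluster 16 in Flox control 1, Flox control 2 and Ms4a3 cKO 2 (128, 480 and 213 cells) and in cluster 20 in Ms4a3 cKO 1 (847 of 1273 cells). The libraries of the Flox group also differed more from each other than those of the cKO group: the standard deviation over genes of the log2 difference between replicates was 0.85 against 0.40 in microglia, 0.93 against 0.50 in monocyte-macrophages and 1.06 against 0.67 in neutrophils. Flox control 2 correlated more closely over genes with both cKO libraries than with Flox control 1. The correlations with Ms4a3 cKO 1 and 2 were 0.980 and 0.985 in microglia, against 0.965 with Flox control 1. In monocyte-macrophages they were 0.969 and 0.980 against 0.952, and in neutrophils 0.843 and 0.878 against 0.824. The libraries therefore did not group by genotype in these classes.

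The first question was whether Htr2b transcript was lower in the cells targeted by the Cre. Htr2b (ENSMUSG00000026228) lies on chromosome 1 at 86099026 to 86111970 on the minus strand of GRCm38, has 4 exons, and carries its 3′ untranslated region in exon 4, at 86099026 to 86099345. In monocyte-macrophages it stood at 84.7 and 131.6 CPM without TMM scaling in the Flox controls and at 11.2 and 26.9 in the cKO libraries, a log2 fold change of -2.65 (SE 0.45, n = 2 libraries per genotype), lower in 2 of 2 cKO libraries. This difference did not pass edgeR's test across all genes (adjusted p = 0.369), whereas DESeq2 gave an adjusted p of 8.53e-07 and edgeR without Flox control 2 gave -2.51 with an adjusted p of 0.0113. The adjusted p was 0.0586 without Flox control 1, 0.451 without Ms4a3 cKO 1 and 0.0565 without Ms4a3 cKO 2. In microglia Htr2b stood at 47.8 and 108.2 CPM in the Flox controls and at 100.1 and 86.2 in the cKO libraries, a log2 fold change of 0.15 (SE 0.33, edgeR adjusted p = 0.854). That value became -0.25 without Flox control 1 and 0.70 with an adjusted p of 0.0192 without Flox control 2. Within monocyte-macrophage cluster 3, a large cluster present in all 4 libraries, Htr2b stood at 69.8 and 153.6 against 29.9 and 61.1 CPM (log2 fold change -1.27, SE 0.40, edgeR adjusted p = 0.506). Neutrophils carried 0 and 13 Htr2b UMIs in the Flox controls and 6 and 5 in the cKO libraries, too few for a test. In other classes Htr2b had a log2 fold change of -2.32 in endothelial cells (SE 0.74, edgeR adjusted p = 0.648; 1.74 and 28.8 against 3.77 and 3.95 CPM, with 1 UMI in Flox control 1), -1.97 in dendritic cells (SE 1.17, 0.671; 4.52 and 13.3 against 0 and 5.34 CPM, with 0 and 2 UMIs in the cKO libraries) and -0.93 in border macrophages (SE 0.44, 0.421), and lay between -0.27 and 0.44 in astrocytes, choroid plexus, fibroblasts and oligodendrocyte cluster 13. The endothelial level of Flox control 1 lay below both cKO libraries, so the direction there rested on Flox control 2.

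A UMI of Htr2b was seen in 43.8 and 40.7% of Flox monocyte-macrophages (median depth 11131 and 7890 UMIs) and in 4.08 and 8.68% of those of the cKO libraries (6261 and 7717 UMIs). With each cell thinned to 1000 UMIs the shares were 7.25 and 10.7% against 0.934 and 2.37%, after 26, 25, 31 and 19 shallower cells were left out. Endothelial cells, taken as a type with little of the transcript, showed a UMI in 0.680 and 5.69% of Flox cells (median depth 3218 and 2620 UMIs) and in 1.11 and 0.949% of cKO cells (2227 and 2162 UMIs), and after thinning in 0.725, 1.72, 0.334 and 0.0636%. Reads of this assay come from the 3′ end of a transcript, and the labels do not say which exon is floxed. If that exon lies upstream of exon 4, a remaining 3′ tag checks nothing about the deletion. Ms4a3 itself (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851, minus strand) had 2, 2, 0 and 5 UMIs in neutrophils, 0, 0, 0 and 6 in monocyte-macrophages and 0, 0, 1 and 0 in microglia.

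**Figure D1:**
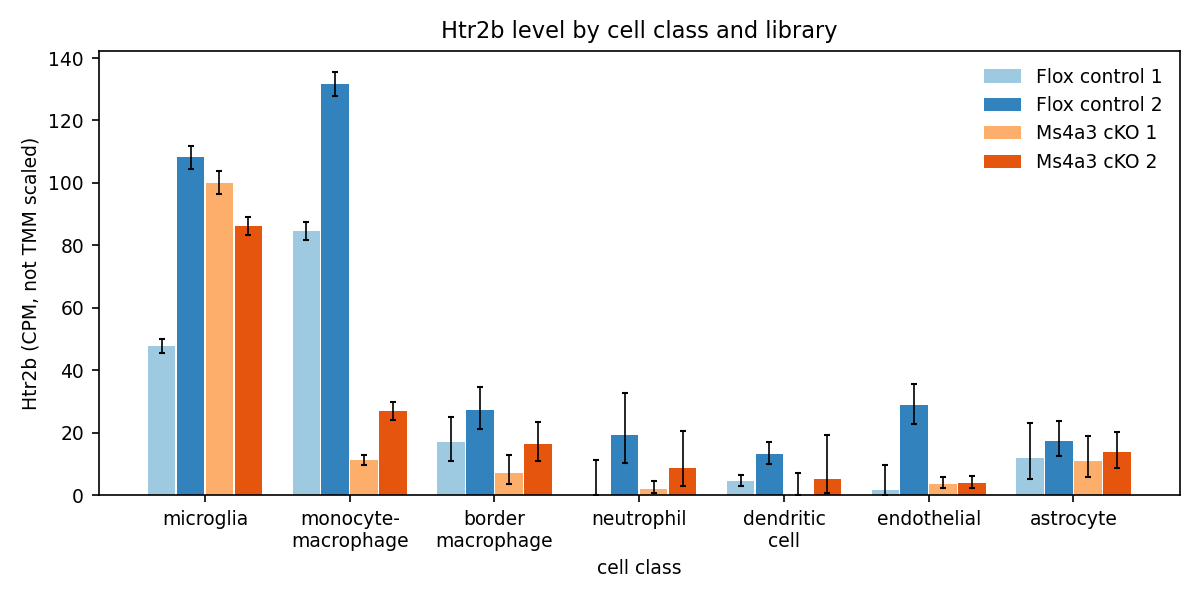
Htr2b level (CPM without TMM scaling, vertical axis) in 7 cell classes (horizontal axis), with 1 bar per library and exact 95% Poisson intervals that cover counting error only. Monocyte-macrophages stand at 84.7 and 131.6 in the Flox controls against 11.2 and 26.9 in the cKO libraries, while the 4 microglia bars lie between 47.8 and 108.2.

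The share of each cell class was compared to learn whether infiltration differed between the genotypes. Microglia made up 38.1 and 26.02% of kept cells in the Flox controls and 30.3 and 38.8% in the cKO libraries (edgeR adjusted p = 0.850). Monocyte-macrophages made up 27.1 and 25.996% against 18.9 and 9.79% (log2 ratio -0.89, SE 0.63, edgeR adjusted p = 0.271), and neutrophils 1.22 and 3.06% against 8.55 and 1.90% (1.29, SE 0.89, edgeR adjusted p = 0.271). Endothelial cells made up 1.11 and 5.03% against 11.5 and 11.7% (1.92, SE 0.80) and T or NK cells 4.47 and 0.752% against 0.322 and 0.549% (-2.58, SE 1.02), each with an edgeR adjusted p of 0.0949. The neutrophil ratio was -0.18 without Ms4a3 cKO 1, and that of T or NK cells was -0.79 without Flox control 1. Fibroblasts made up 2.00 and 5.40% against 0.880 and 1.11% (edgeR adjusted p = 0.147). Of 18 classes tested, 2 passed. Dendritic cells made up 8.65 and 6.19% against 0.840 and 0.614% (log2 ratio -3.35, SE 0.94, edgeR adjusted p = 0.00990), and oligodendrocyte cluster 11 took 0.0151 and 0.0435% (2 and 7 cells) against 4.61 and 8.21% (7.70, SE 1.24, edgeR adjusted p = 6.07e-06). Both are given as numbers of cells in a cluster, which may reflect an expression state as well as a cell type. Genes that define them differed between the genotypes in counts summed over cells. These were Cd209a in dendritic cells, and Phactr3 and Map7d2 in oligodendrocyte cluster 10. The last pair were the 2 of the 10 top genes of cluster 11 that passed, chosen after their values had been seen. Summed counts cannot tell a change inside cells from a change in the mix of cells. The dendritic ratio was -1.05 at Leiden resolution 0.5 (edgeR adjusted p = 0.404) and -2.59 at resolution 2 (0.0999), and its adjusted p was 0.0558 with the replicate number as a block, 0.158 without Ms4a3 cKO 1 and 0.439 without Ms4a3 cKO 2. At resolution 0.5 oligodendrocyte clusters 10 and 11 were not found as classes of their own, so the call of cluster 11 has no value there. Without Flox control 2 the number of classes was 6, and it was 1 without either cKO library. An exact permutation test of 2 against 2 libraries cannot go below 0.333.

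**Figure D2:**
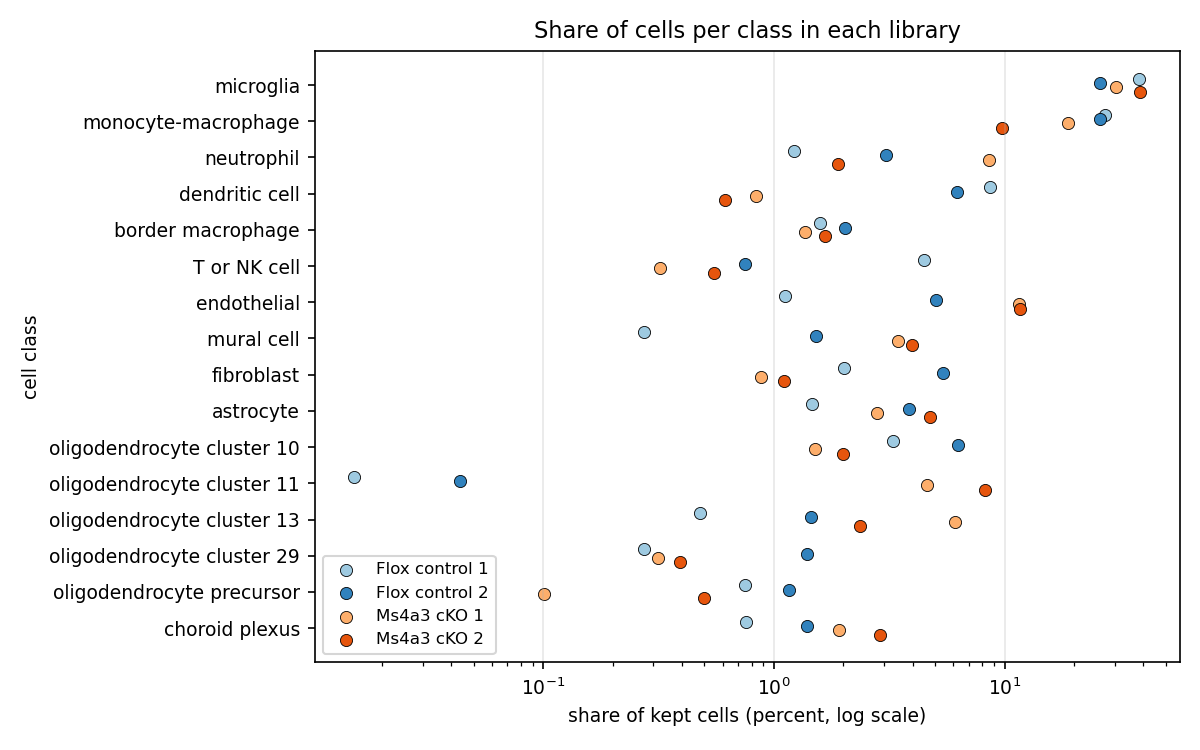
Share of kept cells (percent, log scale, horizontal axis) in 16 cell classes (vertical axis), with 1 point per library. Dendritic cells lie at 8.65 and 6.19% in the Flox controls and at 0.840 and 0.614% in the cKO libraries, and endothelial cells at 1.11 and 5.03% against 11.5 and 11.7%.

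Resident microglia were compared next, as the brain macrophages that an Ms4a3-Cre is meant to leave unrecombined. Of 14223 genes, 0 passed edgeR's test in microglia, with 1546 at an unadjusted p under 0.05, while DESeq2 passed 279 (137 higher and 142 lower in the cKO libraries). The 5 genes with the smallest p did not pass edgeR's test either. Pik3ip1, a negative regulator of PI3 kinase, stood at 3.54 and 3.16 against 36.4 and 37.9 CPM (TMM-scaled; log2 fold change 3.47, SE 0.18, edgeR adjusted p = 0.0799). Ston1, an endocytic adaptor, had a log2 fold change of 2.26 (SE 0.15, adjusted p = 0.176), Ddit4, a stress-induced inhibitor of mTORC1, of 2.68 (SE 0.22, adjusted p = 0.205), and Fkbp5, a co-chaperone of the glucocorticoid receptor, of 1.56 (SE 0.14, adjusted p = 0.205). Mmp12, the macrophage metalloelastase, stood at 139 and 100.9 against 11.2 and 14.3 CPM (-3.23, SE 0.24, adjusted p = 0.177). The count was 27 without Flox control 1 and 4168 without Flox control 2. In simulated counts, with each gene drawn independently, the test recovered 16% of genes changed by 2 fold and 72% of those changed by 4 fold. Recovery in the real data may be lower, since replicate differences shared by many genes were not simulated.

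Of 24 gene lists fixed before the data were examined, 9 fell and 4 rose in microglia by camera with a preset correlation, and 0 passed with an estimated correlation, while 1 passed by fry. Beside these lists, the markers of microglia stood at 29644 and 20180 against 16255 and 17207 CPM, and 0 genes of any list passed when adjusted over all genes. The disease-associated microglia list had a median log2 fold change of -0.84 (camera adjusted p = 6.93e-13), with 7 of 17 members lower when adjusted over the list alone, among them Gpnmb (-1.78, SE 0.19), Lpl, the lipoprotein lipase (-1.51, SE 0.26), Igf1 (-1.66, SE 0.31) and Cd9 (-1.16, SE 0.27). The homeostatic list had a median of -0.73 (1.23e-09), with 7 of 16 lower adjusted over the list alone, among them Olfml3 (-1.08), Siglech (-1.14), Gpr34 (-1.12) and Cst3 (-0.85). Lipid storage and efflux had a median of -0.46 (1.34e-06). Of its 13 members 3 were lower adjusted over the list alone, among them the scavenger receptor gene Cd36 (-1.11) and the lysosomal lipase gene Lipa (-1.002). MHC class II had a median of -1.69 (1.21e-07), with 3 of 7 lower adjusted over the list alone, among them H2-Aa (-4.57) and H2-Eb1 (-3.99). Markers of 2 other classes lay lower in the same cells, dendritic cell markers at 113 and 106 against 72.5 and 69.9 CPM and B cell markers at 104 and 55.7 against 17.4 and 41.7 CPM. Glycolysis and hypoxia had a median of -0.39 (2.60e-05), with 0 of 16 passing adjusted over the list alone and Egln3 at -2.34. The lysosome list had a median of -0.25 (0.00172), with 1 of 18 lower adjusted over the list alone, Lipa, and with Lgmn at 0.46. For these 6 lists the adjusted p was 0.432 with an estimated correlation. Siglech turned to 0.11 within microglial cluster 1, where the homeostatic, disease-associated and MHC class II lists still fell.

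The interferon response list had a median of -1.10 in microglia (camera adjusted p = 4.92e-07; adjusted p = 0.486 with an estimated correlation), with 0 of 17 members passing adjusted over the list alone and the interferon-induced genes Ifi44 at -2.85 and Isg15 at -1.17. MHC class I, with Psmb9 at -0.62 and Tapbp at -1.20, had a median of -0.71 (0.00723; adjusted p = 0.538 with an estimated correlation), and Tapbp stood at 311 CPM in Flox control 1 against 79.1 to 94.8 in the other libraries. The cell cycle list, with Mcm5 at -0.51 and Pcna at -0.33, had a median of -0.21 (0.0434; adjusted p = 0.486 with an estimated correlation). The repair macrophage list rose with a median of 0.79 (0.0488; adjusted p = 0.538 with an estimated correlation), but the growth factor gene Igf1, its member with the smallest p, was lower adjusted over the list alone. Its members Arg1 (0.244 and 11.5 against 100.03 and 48.3 CPM) and Chil3 (1.10 and 8.30 against 41.6 and 14.3 CPM) are abundant in monocyte-macrophages. Markers of that class, Arg1 and Chil3 among them, stood at 734 and 1375 against 2805 and 2208 CPM in microglia. The neutrophil granule list (median 2.57, 0.00271), serotonin receptors and handling (0.88, 0.00723) and the endothelial list (0.09, 0.0330) rose, each with an adjusted p of 0.432 with an estimated correlation. Adjusted over the list alone, 2 of 5, 1 of 6 and 2 of 9 members were higher, and their leading members were scarce. Lcn2 stood at 0.153 and 0.0613 against 4.76 and 1.13 CPM and Ddc, the decarboxylase of serotonin synthesis, at 0.244 and 0.735 against 2.41 and 3.37 CPM. Endothelial markers in microglia stood at 29.7 and 33.7 against 51.8 and 63.0 CPM. The other 11 lists did not pass, with medians of 0.04 for inflammatory cytokines, -0.21 for tissue macrophage maturation, 0.03 for early monocyte, -0.22 for phagocytosis, -0.28 for cholesterol synthesis, -0.23 for oxidative phosphorylation, 0.07 for matrix remodelling, -0.01 for oxidative stress, 0.37 for neutrophil activation, -0.20 for dissociation and stress and -0.16 for reactive astrocyte. For inflammatory cytokines and matrix remodelling the mean and the test were negative, and for reactive astrocyte they were positive.

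Monocyte-macrophages, the infiltrating class, were the second comparison. Of 13106 genes, 0 passed edgeR's test, with 1540 at an unadjusted p under 0.05, while DESeq2 passed 449 (264 higher and 185 lower). The 5 genes with the smallest p each had an edgeR adjusted p of 0.369 and were higher in 2 of 2 cKO libraries. They were Fkbp5 (88.2 and 115 against 621 and 508 CPM, log2 fold change 2.48, SE 0.22), the sulfotransferase gene Sult1a1 (3.37, SE 0.30), Pik3ip1 (3.43, SE 0.35), the bicarbonate transporter gene Slc4a8 (3.27, SE 0.33) and the lectin gene Clec4a2 (2.25, SE 0.24). The count was 108 without Flox control 1, 4391 without Flox control 2, 1 without Ms4a3 cKO 1 and 8 without Ms4a3 cKO 2. In simulated counts 7% of genes changed by 2 fold and 48% of those changed by 4 fold were recovered.

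By camera with a preset correlation 7 of 24 lists fell and 8 rose in monocyte-macrophages, while 0 passed with an estimated correlation and 0 by fry. The early monocyte list had a median log2 fold change of 1.71 (camera adjusted p = 2.97e-12; adjusted p = 0.340 with an estimated correlation), with 10 of 15 members higher adjusted over the list alone and 0 over all genes. Its leading members were F13a1, the coagulation factor XIII subunit (810 and 664 against 2337 and 1867 CPM, 1.51, SE 0.23), Ly6c2, a marker of classical monocytes (60.8 and 51.6 against 151 and 117 CPM, 1.26, SE 0.20), Chil3 (4.24, SE 0.74) and F10 (2.33, SE 0.61). Clusters 5 and 25 held mostly cells of Flox control 1 (2634 and 673 cells, against 270 and 82 in Flox control 2) and few of the cKO libraries. Without them Ly6c2 turned to -0.66, and it was -0.44 within cluster 3 and -0.49 within cluster 15, while F10 was -0.06 within cluster 3. The list's camera adjusted p was 0.01005 without clusters 5 and 25, 0.751 within cluster 3 and 0.955 within cluster 15. The inflammatory list had a median of 0.81 (1.67e-07; adjusted p = 0.340 with an estimated correlation), with 1 of 20 members higher adjusted over the list alone. This was the monocyte chemokine gene Ccl2 (209 and 241 against 495 and 525 CPM, 1.18, SE 0.17), beside Il6 at 2.76, Nlrp3 at 1.44 and Nfkbia at 0.90. Within cluster 3 this list fell (camera adjusted p = 6.35e-06) and Nlrp3 and Nfkbia were -0.16 and -0.58, whereas within cluster 15 it rose (3.64e-06), with Ccl2 at -0.14.

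The disease-associated microglia list had a median of -1.54 in monocyte-macrophages (camera adjusted p = 5.92e-15), with 7 of 17 members lower adjusted over the list alone, among them Lpl, the lipoprotein lipase gene (2417 and 776 against 55.1 and 90.6 CPM, -4.46, SE 0.68), the integrin gene Itgax (-3.11, SE 0.49), the fatty acid carrier gene Fabp5 (-1.15, SE 0.25) and Cd9 (-2.96, SE 0.68). Markers of microglia stood at 8783 and 4565 against 2826 and 3695 CPM in the same cells. Lipid storage and efflux had a median of -1.05 (6.15e-11), with 4 of 13 lower adjusted over the list alone (Lpl, Lipa at -1.45, Fabp5 and Cd36 at -3.15), and MHC class II of -2.49 (7.48e-08), with 5 of 8 lower adjusted over the list alone (Cd74, the invariant chain, at -2.15, H2-Aa at -2.68, H2-Eb1 at -3.26 and H2-Ab1 at -3.12 among them). Each of these 3 lists had an adjusted p of 0.340 with an estimated correlation. MHC class II fell also within cluster 3 (camera with the preset correlation, adjusted p = 5.92e-12) and cluster 15 (2.29e-16). The disease-associated list fell in cluster 3 (4.46e-12) and did not pass in cluster 15 (0.193), but a difference between the 2 clusters was not tested. Phagocytosis (median -0.48, 0.00330; adjusted p = 0.340 with an estimated correlation) had 2 of 15 members lower adjusted over the list alone, Itgav at -1.36 and Cd36. The lysosome list (-0.61, 2.23e-06; adjusted p = 0.442 with an estimated correlation) had 1 of 18, Lipa. Its members Ctsd at -0.76 and Ctsz at -0.50 were positive within cluster 15, at 0.53 and 0.17. Cell cycle (-2.09, 1.13e-05; adjusted p = 0.494 with an estimated correlation) had 0 of 15, and its member Tyms stood at 31.2 CPM in Flox control 1 against 3.29 to 4.25 in the other libraries. Oxidative phosphorylation, with Ndufa4 at -0.71 and Atp5e at -1.09, had a median of -0.34 (0.0149; adjusted p = 0.438 with an estimated correlation).

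Other lists rose in monocyte-macrophages with members that did not share a direction or that are also known from other cell types. The repair list had a median of 0.85 (camera adjusted p = 1.32e-05; adjusted p = 0.345 with an estimated correlation), with Chil3 at 4.24 and the haemoglobin scavenger receptor gene Cd163 at 5.77 higher and Igf1 at -3.41 lower adjusted over the list alone, and with Mrc1 at 2.54. Cd163 and Mrc1 are also markers of border macrophages, whose markers stood at 585 and 754 against 1409 and 1078 CPM in these cells. That sum includes both genes, so it is no separate sign of border macrophages. Over all libraries monocyte-macrophage cluster 4 held Mrc1 at 625, Cd163 at 95.7 and the border macrophage marker Lyve1 at 5.96 CPM. Border macrophage cluster 19 held them at 5525, 1057 and 1781 CPM. The interferon list had a median of 0.69 (0.00710; adjusted p = 0.513 with an estimated correlation), with Ifitm3 (1.42) and Ifi204 (1.00) higher and Bst2 (-1.13) lower adjusted over the list alone. Ifitm3 was -0.37 within cluster 15, and with predicted doublets kept the list had a camera adjusted p of 0.797. The neutrophil granule list had a median of 2.85 (2.02e-06; adjusted p = 0.340 with an estimated correlation) and the neutrophil activation list of 0.32 (0.00219; adjusted p = 0.382 with an estimated correlation), with 4 of 6 and 0 of 15 members higher adjusted over the list alone. Lcn2 stood at 0.0295 and 0.366 against 68.0 and 4.17 CPM and Il1r2 at 3.42 and 7.40 against 238 and 25.8 CPM. Neutrophil markers, Il1r2 among them, stood in these cells at 1503 CPM in Ms4a3 cKO 1 and at 289 to 349 CPM in the other libraries. The dissociation and stress list had a median of 0.24 (0.00366; adjusted p = 0.340 with an estimated correlation), with the early response genes Btg2 (1.68) and Ier2 (1.57) higher adjusted over the list alone. The endothelial list had a median of 1.13 (2.02e-06; adjusted p = 0.340 with an estimated correlation), with 5 of 9 members higher adjusted over the list alone. Ackr1 stood at 0.0885 and 0.225 against 4.11 and 1.42 CPM and Slc2a1 at 0.94, beside endothelial markers at 40.8 and 40.4 against 58.4 and 70.8 CPM. The other 9 lists did not pass, with medians of -0.28 for homeostatic microglia, -0.31 for tissue macrophage maturation, -0.13 for MHC class I, -0.17 for cholesterol synthesis, 0.05 for glycolysis and hypoxia, 0.54 for matrix remodelling, -0.11 for oxidative stress, -0.23 for serotonin receptors and handling and 0.47 for reactive astrocyte. The mean was positive for tissue macrophage maturation, cholesterol synthesis, oxidative stress and serotonin receptors.

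**Figure D3:**
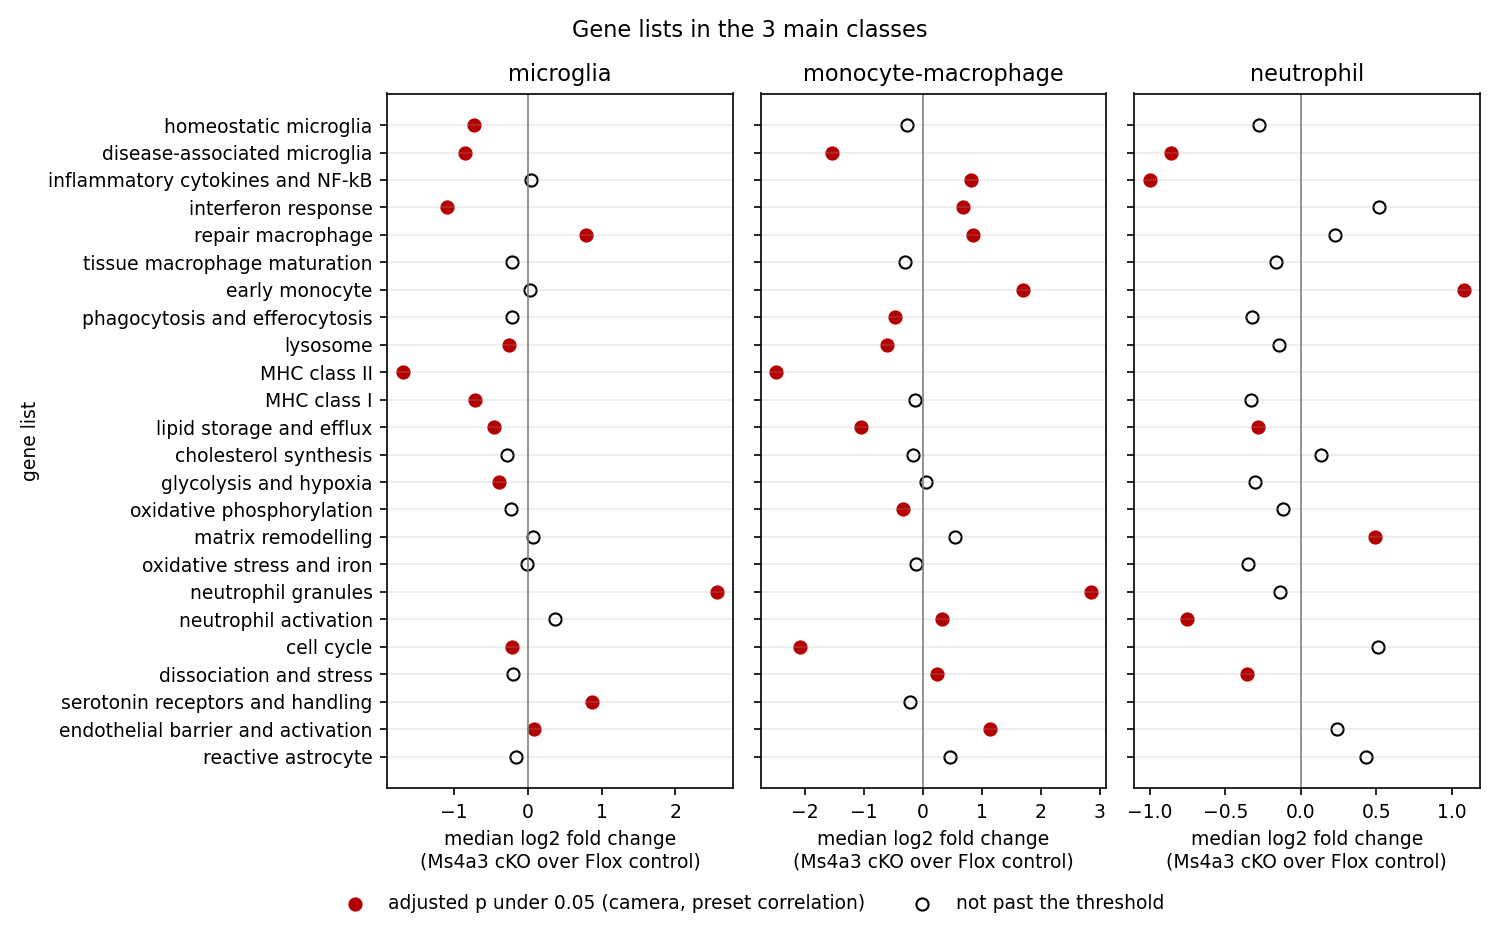
Median log2 fold change (Ms4a3 cKO over Flox control, horizontal axis) of each gene list (vertical axis) in microglia, monocyte-macrophages and neutrophils. Filled points passed camera with the preset correlation, and 0 lists passed with an estimated correlation; MHC class II stands at -1.69 in microglia and -2.49 in monocyte-macrophages.

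Neutrophils, which derive from the Ms4a3 lineage, were the remaining main class. Of 6518 genes, 0 passed edgeR's test, with 479 at an unadjusted p under 0.05, while DESeq2 passed 63 (30 higher and 33 lower). The 5 genes with the smallest p did not pass. Itgax, the integrin subunit CD11c, stood at 210 and 214 against 10.3 and 5.17 CPM (log2 fold change -4.59, SE 0.41, edgeR adjusted p = 0.0982), and the metalloproteinase gene Mmp19 at 3.62 and 8.24 against 228 and 153 CPM (4.81, SE 0.50, edgeR adjusted p = 0.0982). The stefin-like gene Cstdc5 stood at 0 and 1.37 against 894 and 313 CPM (edgeR adjusted p = 0.0982), Klf9 had a log2 fold change of 3.13 (SE 0.39, edgeR adjusted p = 0.208), and Stfa2, which had 0 UMIs in both Flox libraries, was at least 53.2-fold higher in Ms4a3 cKO 1 and at least 23.02-fold higher in Ms4a3 cKO 2 against a floor of 3 UMIs per Flox library (edgeR adjusted p = 0.208). Cstdc5 and Stfa2 belong to a family of near-identical copies, so their counts are uncertain. Cstdc5 is among the 10 top genes of cluster 20, which held 33 and 13 cells in the Flox controls against 847 and 77. Within cluster 16 alone, Cstdc5 had a log2 fold change of 4.54 (SE 0.92, edgeR adjusted p = 0.143). Stfa2 has no usable fold change there, since it had 0 UMIs in both Flox libraries. The count was 24 without Flox control 1, 36 without Flox control 2, 5 without Ms4a3 cKO 1 and 87 without Ms4a3 cKO 2. In simulated counts 2% of genes changed by 2 fold and 28% of those changed by 4 fold were recovered.

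Of 22 lists measured in neutrophils, 5 fell and 2 rose by camera with a preset correlation, 0 passed with an estimated correlation and 4 passed by fry; camera's count was 13 without Flox control 1 and 11 without either cKO library. Neutrophil markers stood at 20039 CPM in Flox control 2 against 59892 to 89197 CPM in the other 3 libraries. The inflammatory list had a median of -1.002 (camera adjusted p = 4.32e-06), with 5 of 17 members lower adjusted over the list alone and 0 over all genes. Among them were the cytokine gene Tnf (1467 and 2290 against 310 and 498 CPM, -2.22, SE 0.45), the chemokine gene Ccl3 (-2.04, SE 0.45), Il1a (-1.61) and Ptgs2, which encodes the inducible cyclooxygenase (-2.17). Neutrophil activation had a median of -0.75 (1.28e-05), with 4 of 15 lower adjusted over the list alone, led by Siglecf (225 and 247 against 29.6 and 49.95 CPM, -2.62, SE 0.38). The disease-associated microglia list had a median of -0.86 (2.43e-08; 3 of 15 lower adjusted over the list alone, Itgax, Gpnmb at -1.71 and Csf1 at -1.88) and dissociation and stress of -0.36 (1.87e-04; 2 of 15, the transcription factor genes Atf3 at -1.88 and Fosb at -2.01). For these 4 lists the adjusted p was 0.261 with an estimated correlation. Lipid storage had a median of -0.28 (0.00284; adjusted p = 0.310 with an estimated correlation), with 1 of 10 lower adjusted over the list alone, Cd36 at -3.50. The early monocyte list rose with a median of 1.08 (0.00984; adjusted p = 0.578 with an estimated correlation), with 4 of 13 members higher and 1 lower adjusted over the list alone. These included F10 (1.64), F13a1 (3.04) and Hp (1.83) on the higher side and Itga4 (-1.72) on the lower, beside monocyte-macrophage markers, F13a1 among them, at 5124 and 2004 against 11584 and 16059 CPM. Some of these markers were abundant in neutrophil cluster 20, which held 33 and 13 cells in the Flox controls against 847 and 77. Over all libraries that cluster held Chil3 at 5128, Ifitm6 at 3497 and Plac8 at 1374 CPM, but Ccr2 at 39.2 and Ms4a4c at 14.5 CPM. The marker sum is therefore no clear sign of monocyte RNA. Matrix remodelling had a median of 0.50 (0.0160; adjusted p = 0.354 with an estimated correlation), with 1 of 14 higher adjusted over the list alone, Mmp19. The other 15 lists did not pass, with medians of -0.27 for homeostatic microglia, 0.52 for interferon, 0.23 for repair, -0.17 for tissue macrophage maturation, -0.32 for phagocytosis, -0.14 for lysosome, -0.33 for MHC class I, 0.13 for cholesterol synthesis, -0.31 for glycolysis and hypoxia, -0.12 for oxidative phosphorylation, -0.35 for oxidative stress, -0.14 for neutrophil granules, 0.51 for cell cycle, 0.24 for endothelial and 0.44 for reactive astrocyte. The test of the interferon list was negative, and the mean and test of the granule list were positive.

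**Figure D4:**
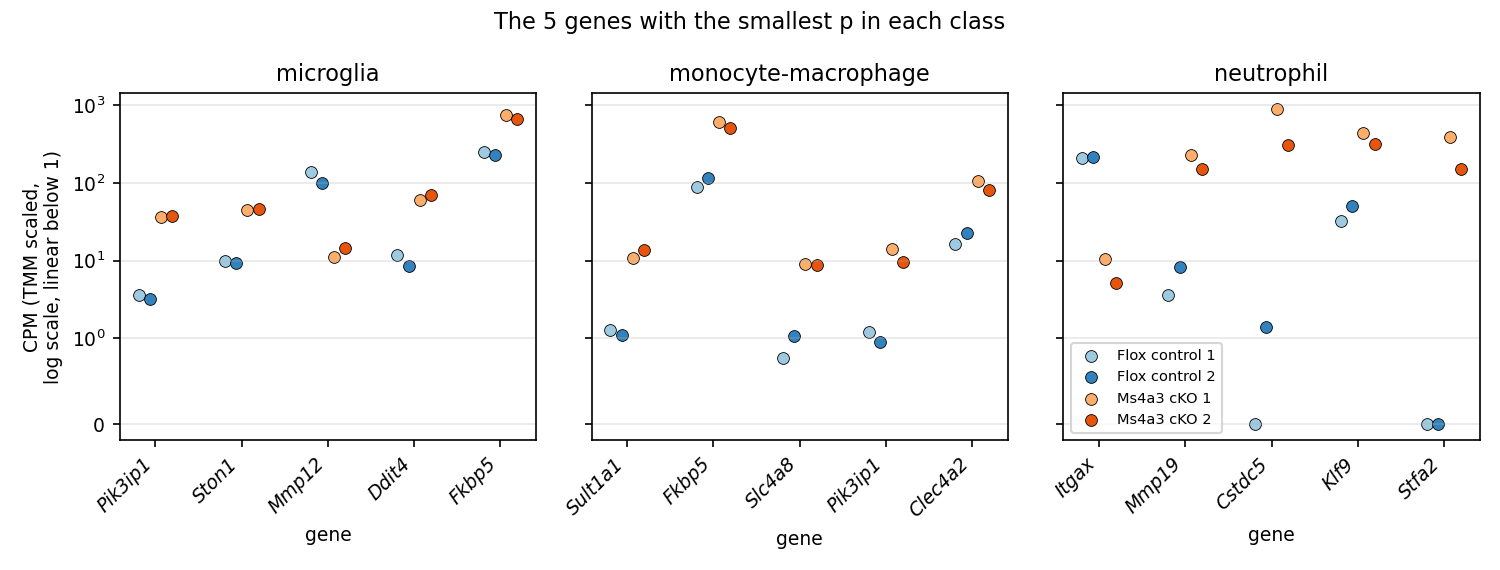
Level (TMM-scaled CPM, log scale that is linear below 1, vertical axis) of the 5 genes with the smallest p in each main class (horizontal axis), with 1 point per library. Fkbp5 stands at 249 and 232 against 749 and 666 in microglia and Itgax at 210 and 214 against 10.3 and 5.17 in neutrophils; none of these genes passed edgeR's test.

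The design set infiltrating against resident cells, so the difference between the genotype effects of the 2 classes was tested directly. Of 14745 genes, 0 passed edgeR's interaction test, with 1440 at an unadjusted p under 0.05; the count was 100 without Flox control 1 and 1218 without Flox control 2. Htr2b had an interaction of -2.95 on the log2 scale (SE 0.51, edgeR adjusted p = 0.312), that is, its log2 fold change (cKO over Flox) was lower in monocyte-macrophages than in microglia. In simulated counts of 12847 genes this test recovered 0% of genes changed by 2 fold and 26.3% of those changed by 4 fold.

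Classes outside the main comparison differed as well. Border macrophages, which line the meninges and vessels, passed 104 of 8900 genes (67 higher and 37 lower in the cKO libraries) by edgeR. The adhesion molecule gene Jaml rose by 5.67 on the log2 scale (SE 0.33, adjusted p = 9.18e-04), Gprc5b by 4.29 (SE 0.30) and Ddit4 by 4.26 (SE 0.31), the last pair each with an adjusted p of 0.00164. Fabp5 fell by 2.06 (SE 0.19, adjusted p = 0.00375), Igf1 by 2.16 (SE 0.22, adjusted p = 0.00862) and Cd4 by 1.87 (SE 0.21, adjusted p = 0.0104). Oligodendrocyte cluster 10 passed 173 of 10218 genes (110 higher and 63 lower), led among the higher genes by the lipid droplet gene Plin4 (5.48, SE 0.29), the cell cycle inhibitor gene Cdkn1a (4.24, SE 0.25) and Sphkap (7.69, SE 0.47), each with an adjusted p of 0.00115. The lower genes were led by Jph4 (-2.32, SE 0.21, adjusted p = 0.00415), Lyz2 (-2.01, SE 0.18, adjusted p = 0.00426) and Enpp6 (-1.64, SE 0.17, adjusted p = 0.00819). Over all libraries Lyz2 stood at 241 CPM in this cluster, against 14200 to 52970 CPM in the monocyte-macrophage clusters. Whether its UMIs came from oligodendrocytes was not tested. In astrocytes Mfsd2a rose by 2.71 (SE 0.25) and Nrep and Ecrg4 fell by 3.30 (SE 0.30) and 3.91 (SE 0.38), each with an adjusted p of 0.0339. In dendritic cells Fkbp5 rose by 2.53 (SE 0.27) and Ston1 by 5.47 (SE 0.60), and Cd209a fell by 3.51 (SE 0.39), each with an adjusted p of 0.0399. Choroid plexus, endothelial cells, fibroblasts, neuroblasts and oligodendrocyte cluster 13 passed 0 genes by edgeR, with 462, 804, 1144, 414 and 977 at an unadjusted p under 0.05 and 24, 73, 196, 0 and 70 by DESeq2. Over these 9 classes the count was 283, against 3173 without Flox control 1, 9427 without Flox control 2, 142 without Ms4a3 cKO 1 and 185 without Ms4a3 cKO 2. Without Ms4a3 cKO 1 and 2 in turn, oligodendrocyte cluster 10 passed 10 and 13 genes, border macrophages 11 and 45, astrocytes 0 and 0, and oligodendrocyte cluster 13 105 and 87. With the replicate number as a block choroid plexus passed 64 (39 higher and 25 lower) and astrocytes 0, and at Leiden resolution 2 border macrophages passed 39 (29 higher and 10 lower) and dendritic cells 0.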

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

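The test of lists between classes was chosen after the lists of each class had been seen. The interferon response list stood out because it passed camera in opposite directions in 2 classes: its median log2 fold change was -1.10 in microglia and 0.69 in monocyte-macrophages, and the median of the interaction between them was 1.78 (camera adjusted p = 1.76e-08; adjusted p = 0.417 with an estimated correlation). In monocyte-macrophages the list did not pass with predicted doublets kept (camera adjusted p = 0.797) or without clusters 5 and 25 (0.180). Unnamed cluster 21, led by the interferon-induced genes Rsad2, Ifit2 and Ifit3, held 477 and 235 cells in the Flox controls against 142 and 106, and belonged to neither class.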

How the results depend on the processing

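The fits of single clusters, of monocyte-macrophages without clusters 5 and 25, and of the crossed block, and DESeq2 for Htr2b, were chosen after the results were seen; all other alternatives were planned. Each group held 2 libraries, and with 1 library left out the lone sample is assumed to vary like the other group. Where no cause is given, the cause was not tested.

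Genes passing in microglia, monocyte-macrophages and neutrophils, 0 each, became 279, 449 and 63 with DESeq2, 106, 384 and 174 with no filter on low counts, and 0 to 4168, 1 to 4391 and 5 to 87 with a library left out. Thinning gave 8 in microglia, cluster 3 alone 1 and cluster 15 alone 108 in monocyte-macrophages, and cluster 16 alone 2 in neutrophils. Other scalings, filters, doublet and clustering settings gave 0. Replicates share only a number: same-number deviations correlated at -0.147, -0.170 and 0.241, and the replicate block gave 6, 2 and 28 genes; the crossed block gave 17, 90 and 0. In other classes 283 became 1039 with DESeq2, 3579 with no filter, 99 at resolution 0.5, and 142 to 9427 with a library left out. The interaction, 0 genes, gave 141 with no filter, 18 without clusters 5 and 25, and 0 to 1218 with a library left out. Lists, 13 (4 up, 9 down), 15 (8, 7) and 7 (2, 5), were 0, 0 and 0 with an estimated correlation and 1, 0 and 4 by fry, 8 in microglial cluster 6 (0, 8), 7 in cluster 3 (1, 6) and 8 in cluster 15 (6, 2) of monocyte-macrophages, in microglia 1 up and 9 down in cluster 1 and 2 and 8 with doublets kept, and 12 to 15, 14 to 18 and 9 to 13 with a library left out. Classes that differed in share, 2, were 1 among myeloid cells, 0 at resolution 0.5, 1 at resolution 2, 1 with the replicate block, and 1 to 6 with a library left out. Htr2b in monocyte-macrophages ranged from -3.40 to -2.15 with a library left out and was -2.64 with DESeq2 (adjusted p = 8.53e-07), over adjusted p from 8.53e-07 to 0.506.

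Of the named genes, 1219 settings kept direction and side of the threshold, 263 moved past it and 27 reversed. Reversed in monocyte-macrophages were, within cluster 3, Clec4e -0.40, F10 -0.060, Ly6c2 -0.44, Nfkbia -0.58, Nlrp3 -0.16, Trem1 -0.22 and Rrm2 0.93; within cluster 15, Ccl2 -0.14, Ctsd 0.53, Ctsz 0.17, Ifi27l2a -1.21, Ifitm3 -0.37, Ly6c2 -0.49, Ndufa1 0.12, Ndufs6 0.10 and Rrm2 0.78; and without clusters 5 and 25, Birc5 0.11, Ly6c2 -0.66 and Tyms 0.033. In microglia they were, within cluster 1, Birc5 0.22, Rrm2 0.0026 and Siglech 0.11; without Flox control 1, Htr2b -0.25, Mmp8 0.021 and Nlrc5 0.18 (with each library left out, -0.25 to 0.70, -0.82 to 0.021 and -1.76 to 0.18); and thinned, Mmp8 0.31. In neutrophils Plau was 0.35 when thinned.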

Other observations

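The fits within single clusters, the tests of Htr2b, that of white matter and that of a microglial mix in other classes were chosen after the results were seen. The list of 20 glucocorticoid-responsive genes was written after 12 of them had been seen to be higher in the cKO libraries. Medians and tests of the whole list therefore rest in part on that choice. The test of its other members was written after their medians had been seen. Its tests in 6 non-myeloid classes, in endothelial cells, in microglial cluster 1 and in oligodendrocyte cluster 11 were written before those values were seen. Genes named here were picked after their values had been seen.

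Monocyte-macrophage cluster 15, led by the monocyte genes Chil3, Plac8 and Ccr2, passed 108 of 6566 genes by edgeR (52 higher and 56 lower in the cKO libraries; 104 and 235 against 894 and 118 cells). Ms4a8a (3.11, SE 0.31), the cathepsin gene Ctsl (2.26, SE 0.25) and the proteoglycan gene Sdc4 (3.52, SE 0.39) rose, and Adgre4 (-4.23, SE 0.37), a receptor gene of monocytes and macrophages, Ighm (-5.97, SE 0.66) and Abcg3 (-4.62, SE 0.52) fell, each with an adjusted p of 0.0143. Of the neutrophil markers fixed in advance 7 were measured, and 5 rose (Retnlg 8.11, Cxcr2 7.01, S100a9 6.34, S100a8 5.27, Mmp8 3.57). Of the MHC class II list 6 were measured, and 5 fell, with H2-Ab1 at -2.82 and Cd74 at -2.70. The list had an adjusted p of 2.29e-16 by camera with the preset correlation, and an estimated correlation was not tried within this cluster. The cell mix of this cluster was not tested. Within cluster 3 the gene that passed was Fkbp5 (2.35, SE 0.20, adjusted p = 0.0308), and within neutrophil cluster 16 Mmp19 rose (4.89, SE 0.37, adjusted p = 0.0288) and Itgax fell (-4.27, SE 0.37, adjusted p = 0.0324).

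A list of glucocorticoid-responsive genes had a positive median log2 fold change (cKO over Flox) in each of the 12 classes tested, with Fkbp5 between 1.02 and 3.42 and Zbtb16 between 1.30 and 4.70, though its member Tsc22d3 stood at -0.38 in microglia, 0.32 in monocyte-macrophages and -0.22 in neutrophils. The median of the list was 1.11 in microglia, 1.46 in monocyte-macrophages, 1.35 in neutrophils, 1.69 in border macrophages, 1.87 in dendritic cells and 1.70 in oligodendrocyte cluster 10. Of the measured members 12 of 19 passed in oligodendrocyte cluster 10, 6 of 16 in border macrophages and 1 of 15 in dendritic cells, and 0 in the other 9 classes, among them microglia, monocyte-macrophages and neutrophils. The members not seen before had medians of 0.37, 0.35, -0.05, 0.33, 0.88 and 1.07. Tested alone by camera with the preset correlation, these members did not pass in microglia (adjusted p = 0.0825), neutrophils (0.0581) or border macrophages (0.0825) and passed in monocyte-macrophages (0.0102), dendritic cells (0.00755) and oligodendrocyte cluster 10 (7.65e-12). With an estimated correlation they passed in no class (adjusted p from 0.142 to 0.310), and in neuroblasts they were too few to test. Free RNA from microglia is argued against, for the list as a whole, by the level in endothelial cells, a median of 3.74 times that in microglia in the cKO libraries (quartiles 1.14 and 5.64). Its members Fkbp5 and Bcl6 stood lower, at 0.415 and 0.271 times, and other myeloid classes were not compared. An effect inside the Ms4a3-Cre lineage alone is argued against by medians of at least 0.5 in 6 of 6 classes outside it (0.86 to 1.33, and 0.67 to 1.09 for the members not seen before). A different mix of microglial clusters was also set against the medians of the same 6 classes, whose lowest was 0.858. That test could not decide anything, since microglial clusters do not enter the fits of those classes. For the higher median in microglia such a mix stays open: within cluster 1 the median was 0.59, above the bound of 0.5 times 1.11 set in advance but not by more than its spread, a requirement that was added to the label after the value was seen. A difference shared by the 2 libraries of a genotype, such as collection day, handling or circulating corticosterone, may also account for it, cannot be told apart from genotype in this design, and was not tested.

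Htr2b was lower in the monocyte-macrophages of both cKO libraries. The lower depth of these libraries is argued against by the share of cells with a UMI after thinning to 1000 UMIs, at most 2.37% in a cKO library and at least 7.25% in a Flox library. Free RNA as the source of the Flox UMIs is argued against by endothelial levels of 0.0206 and 0.219 times those of monocyte-macrophages in Flox control 1 and 2. A different mix of macrophage clusters could account for part of the change, since it was -1.27 within cluster 3 (SE 0.40). The change was -2.41 (SE 0.58) without clusters 5 and 25, which held mostly cells of Flox control 1. That fit kept 161, 15 and 104 cells of Flox control 1, in clusters 3, 4 and 15. That fit cannot decide the question, since the mix of the remaining clusters still differed. Cluster 3 held 161 and 2970 cells in the Flox controls against 123 and 288, and cluster 4 held 15 and 626 against 1769 and 1035. Htr2b stood lower in cluster 4 than in cluster 3 in Flox control 2 and in both cKO libraries. Cluster 15 held 5, 3, 5 and 0 UMIs, too few to test. Deletion by the Cre, which the design names, was not tested and stays open.

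Oligodendrocyte cluster 11, led by Ptgds and Apod, held 2 and 7 cells in the Flox controls against 686 and 1257. More white matter in the cKO suspensions stays open: the highest share of oligodendrocyte cluster 10 in a cKO library, 1.99%, lay below its lowest in a Flox library, 3.30%, but cells that changed from cluster 10 to cluster 11 would lower it too, and cluster 13 took 0.477 and 1.45% against 6.09 and 2.36%. The glucocorticoid-responsive genes as what separates the clusters also stay open, since their median log2 ratio of cluster 11 over cluster 10 was 0.45 and 0.41 in the cKO libraries, between the bounds set in advance. Within cluster 10, Phactr3 (1.67, adjusted p = 0.0146) and Map7d2 (1.61, adjusted p = 0.0116) rose in the cKO libraries, while the other 8 of the 10 top genes of cluster 11 did not pass (adjusted p from 0.106 to 0.898). A change of state and a change in number cannot be told apart.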
